A study of Mus musculus with 4 samples.

How the data were processed

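Bone marrow RNA of mice was measured on 4 Affymetrix arrays, 1 for each of 4 groups: control, cisplatin (a platinum drug that crosslinks DNA and is toxic to blood-forming marrow), Astragalus membranaceus (a root used in Chinese medicine, called astragalus here) and electro-acupuncture. Per the labels' protocols, tibias were taken after 2 weeks of treatment, the marrow was spun out of the bones, RNA was extracted with Trizol, and biotin-labelled cRNA was made from 6 ug of total RNA. The series design text says that 6 marrow samples were mixed before extraction, and it was read here as 6 per group, which the text does not state outright. Doses are not given in the sources used here. The labels also do not say whether the astragalus and electro-acupuncture mice received cisplatin as well, so each of these groups was compared with both the control and the cisplatin array.

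The deposited values are on a log2 scale, 1 per transcript cluster (the array's unit for a gene or transcript) and array. Per the submitters' processing notes they were made with Affymetrix Expression Console, whose version and summary method are not given in the sources used here. The scale was read from the values, which run from 2.70 to a common ceiling of 19.93, the log2 of about 1000000. The 4 columns have close but not identical quantiles, so they were not forced to one distribution as a set of 4. The ceiling was reached on at least 1 array by 295 clusters and on all 4 by 29 of the genes compared, and a difference of such a gene is not measurable. For arrays without replicates, the number of arrays limits the precision.

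Of 65956 clusters, 32750 were listed in the platform's gene table. Among these, 31258 carried 1 gene symbol and 1492 carried several, and no gene was named from the latter. This left out the clusters of the adult globin chains. The other 33206 clusters are unnamed here. Symbols were updated through a RefSeq gene table of the GRCm38.p6 assembly, used for names, gene types and genomic spans only. It altered the symbol of 1152 clusters and left 30702 named genes. A gene entered the comparisons when its mean over the 4 arrays was at or above 5.235 on the log2 scale, the median of all clusters, which kept 17196 genes. Of the genes with several clusters, numbering 441, the cluster with the highest mean was used.

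Each comparison is a difference of log2 values between 2 arrays. With 1 array per group no test was run and no p-value is given. A gene was counted by size alone, at an absolute log2 difference of at least 1. The fixed comparisons were cisplatin with control, astragalus with cisplatin and electro-acupuncture with cisplatin, and beside them astragalus with control, electro-acupuncture with control and astragalus with electro-acupuncture. Gene lists for marrow cell types, bone and vessel cells, tissue from outside the marrow, stress responses, the cell cycle, signalling and metabolism were written before the data were examined, as were the comparisons, the thresholds and the rule for named genes. Of the 36 lists, 35 had at least 5 members above the floor. A list's median difference was placed among 10000 random lists of the same size drawn from genes of like mean level in 20 bins. It is said to stand apart at a percentile of at most 2.5 or at least 97.5. That percentile describes these arrays and is not a p-value, since the genes of a list are co-regulated and random genes are not.

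The genes named are, for the first 3 comparisons, the 8 with the largest difference in each direction and up to 4 members of each list that stood apart. For the other 3 they are the 5 largest in each direction and up to 2 members per list. Unnamed gene models and antigen receptor V segments were passed over. A fixed set was added whatever its values: Alas2, Epor, Kit, Mpo, Cdkn1a, Mdm2, Gapdh, Actb, Xist and the globin genes with a cluster of their own. Ddx3y belongs to that set too and had no single-gene cluster above the floor.

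For the 512 genes that differed at least 2-fold between cisplatin and control, the share lying nearer the control than the cisplatin value on the astragalus or electro-acupuncture array was counted against the midpoint, with a 95% Wilson interval that covers counting of genes only. Unchanged arrays were simulated 100 times with equal noise and with cisplatin noise 1.5 and 2 times as large, because the comparisons share arrays. The noise was drawn from the differences between astragalus and electro-acupuncture in genes of like level. It may therefore hold real differences between these 2 groups and is not technical noise alone. Larger control noise and the overlap among protein-coding genes were simulated too, choices made after the counts were seen. The steps were tested on simulated data for cisplatin against control with 17196 genes, noise with an SD of 0.2 and 200 altered genes per run. At a true 4-fold difference 200 of 200 genes were counted, at 2-fold 110, and at 1.5-fold 17, with 6, 4 and 6 unaltered genes counted beside them. For 35 unaltered lists 0 stood apart, and with a shift of 0.5 all 35 did. This noise was independent between genes and alike at all levels, so these figures do not estimate false counts on the real arrays.

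The alternatives planned in advance were centring each array on its median, quantile normalization, removal of a loess trend of the difference on level (span 0.3), no filter, a filter at the 75th percentile, a filter on the highest array, and the mean of a gene's clusters. The setting with protein-coding genes only was added after the data were seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.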

Results

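The data are 4 marrow expression profiles of mice, from 1 array each of control, cisplatin, astragalus and electro-acupuncture. Over all 65956 clusters the median log2 level was 5.27 in control, 5.26 in cisplatin, 5.15 in astragalus and 5.31 in electro-acupuncture. The astragalus array had a wider range, with 7.20 between its 5th and 95th percentiles against 6.81, 6.83 and 6.80 in the control, cisplatin and electro-acupuncture arrays. Every difference below has no replicate check, because each group has 1 array, and the number of arrays limits the precision.

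The comparison of cisplatin with control asks which marrow genes differ after the drug. Platelet genes and most bone-forming and fat cell genes were higher in the cisplatin array and early B cell genes were lower. All 17 genes of the megakaryocyte and platelet list were higher, with a median 2.16-fold difference, and 10 of them were at least 2-fold higher. In the list of pro-B and pre-B cell genes 17 of 18 were lower, with a median 2.31-fold difference, and 10 were at least 2-fold lower. Bglap2 and Bglap, which encode osteocalcin of bone matrix, were 49.2-fold and 26.4-fold higher. In number, 512 of 17196 genes differed at least 2-fold, 346 higher and 166 lower. Simulated unchanged arrays of equal noise, drawn from the differences between astragalus and electro-acupuncture, gave 216 such genes.

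The platelet genes with the largest differences were Thbs1 (thrombospondin, 8.52-fold), Ppbp (a platelet chemokine precursor, 5.94-fold), Gp5 (a subunit of the von Willebrand factor receptor, 4.17-fold) and Pf4 (platelet factor 4, 3.89-fold). Of the 15 osteoblast and stroma genes, 13 were higher, with a median log2 difference of 1.16. Among them Sparc, a matrix protein of bone, was 7.73-fold higher and Col1a1, a chain of type I collagen, 4.86-fold. Bglap and Bglap2 are near-identical copies, so the split of the signal between them is uncertain. Fat cell genes had a median of 0.58, with 7 of 10 higher and 3 lower, among them Scd1 (a fatty acid desaturase) 5.10-fold, Fabp4 (a fatty acid carrier) 4.06-fold, Adipoq (adiponectin) 2.75-fold and Lpl (lipoprotein lipase) 2.68-fold higher. Both medians depend on the filter: without it they were 0.72 for stroma and 0.27 for fat, and at the 75th percentile 2.17 and 1.44. Endothelial genes had a median of 0.26, with Vwf 1.96-fold, Stab2 1.53-fold, Kdr 1.39-fold and Cdh5 1.34-fold higher. Vwf also belongs to platelets. The skeletal muscle list, which stands for tissue carried in from outside the bone, had a median of -0.06 over 8 of its 17 genes. Their median levels were 5.745 in control and 5.545 in cisplatin, close to the floor. This list says nothing of bone tissue in the samples. The cartilage list was not used because only 4 of its members were above the floor.

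Among lymphoid genes, Il7r, the receptor through which early lymphocytes receive interleukin 7, was 4.14-fold lower. Cecr2 was 3.53-fold lower, Sox4 2.77-fold and Bach2 2.75-fold, the last 2 being transcription factors of early B cells. Mature B cell genes had a median of -0.33, with 15 of 16 lower. Spib was 2.93-fold, Fcrla 2.66-fold, Blk 2.01-fold and Tnfrsf13c, the receptor for the survival factor BAFF, 2.00-fold lower. Medians of other lymphoid lists were 0.13 for T cells, -0.01 for NK and cytotoxic cells and 0.03 for plasma cells. The T cell and NK genes had median control levels of 5.61 and 5.615, close to the floor of 5.235. A loss of these cells could therefore hardly show.

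The neutrophil primary granule list, which also holds regulators and other genes of promyelocytes, had all 12 genes higher, with a median of 0.68. They included Igfbp4 (a secreted binding protein of insulin-like growth factors, also made by stromal cells, 2.71-fold), Ctsg (cathepsin G, 2.48-fold), Mpo (myeloperoxidase, 2.14-fold) and Ms4a3 (2.01-fold). Monocyte and macrophage genes had a median of 0.17, with Vcam1 2.33-fold, Hmox1 (heme oxygenase) 2.20-fold and Mrc1 1.54-fold higher. Fcgr1 was at 5.35 against 4.66 in control, a value under the floor that the filter set for the mean, so the size of its difference is uncertain. This list no longer stood apart with the loess trend removed or with the filter at the 75th percentile, at medians of 0.15 and 0.29. Red cell membrane and enzyme genes were lower in 15 of 21 cases, with a median of -0.21. Car1 (carbonic anhydrase 1) was 2.03-fold lower, Kel 1.92-fold, Bpgm 1.80-fold and Rhd 1.54-fold. Of the mitotic genes in the G2/M list, 28 of 31 were lower, with a median of -0.40. Anln was 1.89-fold, Kif11 1.79-fold, Cenpf 1.73-fold and Top2a (topoisomerase 2) 1.72-fold lower.

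Stress genes were higher in part. The NRF2 and metallothionein list had a median of 0.62, with Mt2, a metal-binding protein, 2.99-fold, Gstm1 2.38-fold and Gstp1 (both glutathione transferases) 1.89-fold higher. The immediate early and heat shock list had a median of 0.30, with Fos 5.74-fold, Dusp1 2.13-fold and Ier2 1.87-fold higher. Jun was at 6.17, against a value under the floor in control. The p53 target list had a median of 0.06 and did not stand apart. Within it Cdkn1a, the cell cycle inhibitor that p53 induces, was 4.35-fold higher, while Mdm2, the p53 ubiquitin ligase, was at 9.18 against 9.22 in control. Respiratory chain genes (the oxidative phosphorylation list) had a median of 0.27, with Cox5b 2.14-fold, Cox7a2 2.11-fold, Ndufb9 1.92-fold and Ndufa4 1.89-fold higher. Genes of hypoxia and glycolysis had a median of 0.20, with Tpi1 1.72-fold, Pgk1 and Ldha each 1.59-fold and Gapdh 1.54-fold higher. Without the filter on low values the hypoxia list did not stand apart, at a median of 0.14, and with the filter at the 75th percentile its median was 0.40.

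The remaining genes with the largest differences were members of families with close copies. Apol11b, Apol11a and Apol10a, of the apolipoprotein L family, were 41.6-fold, 13.5-fold and 8.75-fold higher. Stfa2l1 and Stfa2, stefins that inhibit cysteine proteases, were 11.5-fold and 9.19-fold higher. Both belong to the neutrophil secondary and tertiary granule list, whose other 19 members were under 2-fold. The lowest were the spliceosomal RNA gene Rnu5g (8.94-fold lower), Mir1955 (5.28-fold), Mir378c (4.79-fold), the interferon-inducible gene Ifi209 (4.76-fold), Mir15a (3.39-fold) and the small nucleolar RNA gene Snord17 (3.29-fold).

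In all, 14 of 35 lists stood apart, 10 above and 4 below random lists. Lists that did not, besides those above, had medians of -0.03 (hemoglobin and heme), -0.09 (erythroid regulators), 0.01 (neutrophil secondary and tertiary granule), -0.09 (dendritic cell and antigen presentation), 0.02 (eosinophil), -0.13 (basophil and mast cell), 0.08 (stem and progenitor cell) and 0.24 (osteoclast). Further medians were -0.10 (DNA repair), -0.03 (G1/S and DNA replication), 0.08 (interferon-stimulated), 0.05 (inflammatory cytokine and NF-kB target), 0.35 (ribosomal protein), 0.11 (apoptosis), 0.01 (haematopoietic cytokine and receptor) and 0.09 (JAK-STAT and MAPK signalling). Of the 512 genes, 192 were protein-coding, 136 of them higher and 56 lower, and 184 were pseudogenes, 172 of them higher.

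**Figure D1:**
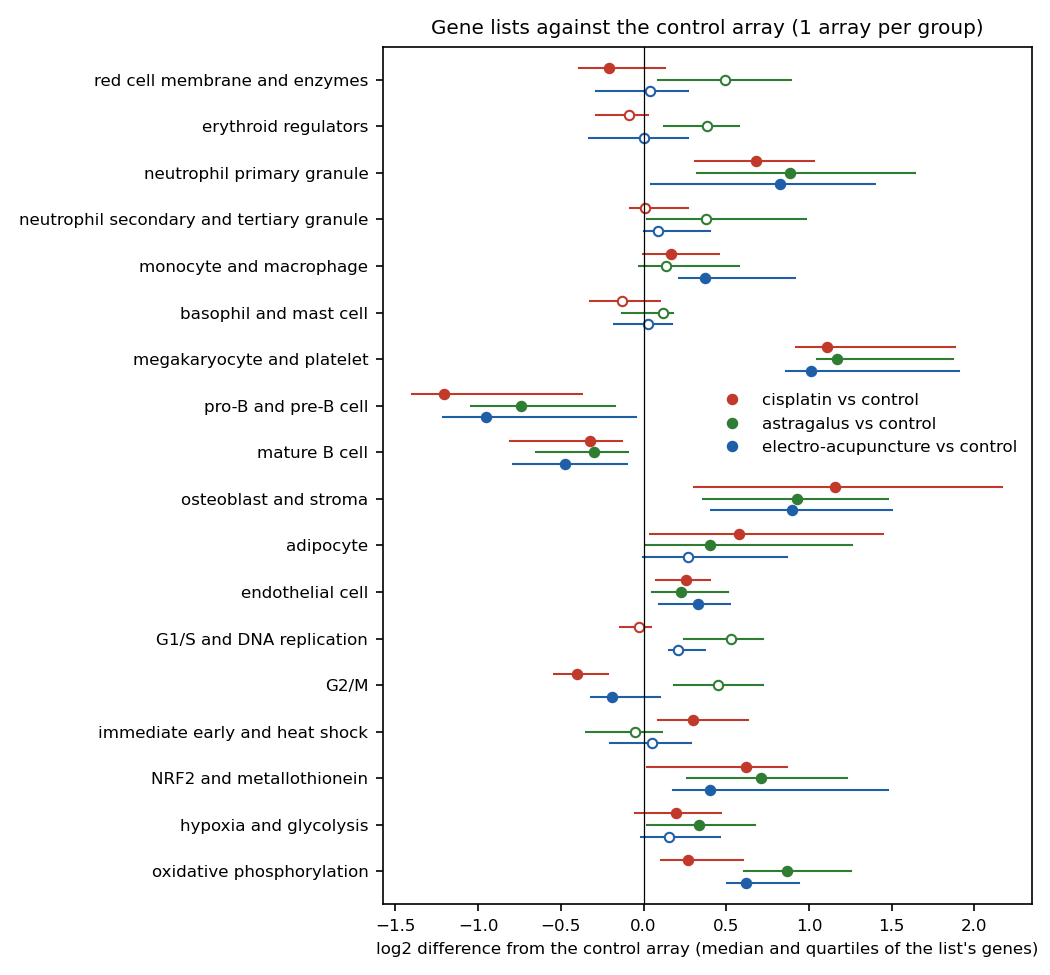
Median log2 difference from the control array (points) with the quartiles of each list's genes (lines), for the cisplatin, astragalus and electro-acupuncture arrays. Filled points stood apart from random lists of like level. Platelet genes lie at 1.11, 1.17 and 1.01, and early B cell genes lie below 0, on the 3 arrays.

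The comparison of astragalus with cisplatin asks where marrow after astragalus differs from marrow after the drug. Genes of dividing cells and red cell membrane and enzyme genes were higher in the astragalus array. All 31 G2/M genes were higher, with a median 1.83-fold difference, and all 21 red cell membrane and enzyme genes were higher, with a median of 1.71-fold. Most immediate early genes and some osteoblast and stroma genes were lower, led by Fos at 10.3-fold lower. In number, 674 genes differed at least 2-fold, 344 higher and 330 lower.

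Mitotic genes with the largest differences were Ube2c (2.62-fold), Kif11 (2.46-fold), Cdk1 (the kinase that starts mitosis, 2.31-fold) and Bub1b (a spindle checkpoint kinase, 2.19-fold). Of the G1/S and DNA replication genes 27 of 27 were higher, with a median of 0.64. The ribonucleotide reductase genes Rrm1 and Rrm2 were 2.16-fold and 1.96-fold higher, and the helicase genes Mcm4 and Mcm6 were 1.92-fold and 1.82-fold higher. Red cell genes included Rhag (log2 difference 1.32), Ermap (2.35-fold), the water channel gene Aqp1 (2.30-fold) and Rhd (2.25-fold). The other red cell lists, hemoglobin and heme and erythroid regulators, each had a median of 0.43 and did not stand apart. Respiratory chain genes had a median of 0.57, with Cox7a2 2.06-fold, Ndufa4 2.01-fold, Atp5b 2.00-fold and Ndufa1 1.92-fold higher. Early B cell genes had a median of 0.40, with 15 of 18 higher, among them Il7r (1.64-fold), Cecr2 (1.59-fold), Cd79b (1.57-fold) and Vpreb3 (1.42-fold). None of these B cell genes reached 2-fold.

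Osteoblast and stroma genes had a median of -0.26, with 8 lower and 7 higher. Bglap2 was 3.63-fold, Bglap 3.32-fold, Col1a1 2.57-fold and Sparc 2.33-fold lower. Fat cell genes had a median of -0.18, with Fabp4 1.65-fold, Retn 1.30-fold, Lpl 1.21-fold and Scd1 1.20-fold lower. After quantile normalization or loess the fat cell list no longer stood apart, at medians of -0.17 under both. Immediate early and heat shock genes had a median of -0.37, with 18 of 21 lower, and besides Fos they included Ier2 (2.08-fold) and Zfp36 (2.06-fold). Jun was at 5.11 in astragalus, under the floor, and at 6.17 in cisplatin.

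Other genes with the largest positive differences were Snord72 (5.39-fold), Snord87 (4.11-fold), Gch1 (the first enzyme of tetrahydrobiopterin synthesis, 3.73-fold), Tuba4a (an alpha-tubulin of platelets and other cells, 3.61-fold), Mir378c (3.48-fold), Mir505 (3.41-fold), Pglyrp1 (a neutrophil protein that binds bacterial cell walls, 3.32-fold) and the pseudogene Hadhb-ps (3.32-fold). The lowest genes were the mitochondrial gene ND2 (11.2-fold lower, from 19.79, close to the ceiling, in cisplatin), the mitochondrial transfer RNA gene mt-Tk (9.25-fold) and the small RNA genes Rmrp (6.82-fold), Rn5s (6.41-fold), Rnu5g (6.02-fold), Rnu3b1 and Rnu3b2 (each 5.46-fold). The last 2 had equal levels on each array, so their signals cannot be assigned to one copy.

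Of 35 lists 8 stood apart, 5 above and 3 below random lists, and the medians of the other 27 lay between -0.14 and 0.43. Brighter genes were higher in the astragalus array, and random lists matched in level to the red cell and G2/M lists had medians of 0.29 and 0.30. With the loess trend removed, those 2 lists had medians of 0.47 and 0.54, and the G1/S, respiratory chain and early B cell lists had 0.29, 0.23 and 0.22. With the filter at the 75th percentile the osteoblast and stroma median was -1.18. The share of higher genes among those at least 2-fold different was 51.0% as deposited, 33.7% after quantile normalization and 22.6% after loess. Of the 674 genes 128 were protein-coding, 104 higher and 24 lower, and 155 were snRNA genes, 152 of them lower. A further 201 were pseudogenes, 160 higher and 41 lower.

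The comparison of electro-acupuncture with cisplatin asks the same question for electro-acupuncture. Most immediate early genes and some osteoblast and stroma genes were lower in the electro-acupuncture array, and macrophage, early B cell, replication and respiratory chain genes were higher by small amounts. Bglap2 was 11.8-fold and Bglap 9.38-fold lower, Fos was 6.59-fold lower, and Prg2, the major basic protein of eosinophil granules, was 6.11-fold lower. Respiratory chain genes were higher in 25 of 27 cases, with a median 1.33-fold difference. In number, 673 genes differed at least 2-fold, 228 higher and 445 lower.

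The macrophage list had a median of 0.23 with 18 of 20 genes higher. It included the complement gene C1qc (1.73-fold), the mannose receptor gene Mrc1 (1.73-fold) and Cd68 (1.61-fold). Its member C1qb was at 6.25 against 5.18 in cisplatin, a value under the floor. Early B cell genes had a median of 0.26 with 17 of 18 higher, among them Dntt (terminal transferase, 2.13-fold), Vpreb3 (1.48-fold) and Sox4 (1.39-fold). The recombinase gene Rag2 was at 5.93 against 5.13 in cisplatin, also under the floor. Replication genes had a median of 0.30, with Mcm4 1.55-fold, Mcm6 1.53-fold, Rrm1 1.48-fold and Uhrf1 1.39-fold higher. Mitotic genes had a median of 0.20, with Plk1 1.66-fold, Kif11 1.57-fold, Ube2c 1.55-fold and Bub1b 1.52-fold higher. After quantile normalization the mitotic list no longer stood apart, at a median of 0.21. The replication median was 0.19 after loess. Among respiratory chain genes Ndufb9 was 2.00-fold, Atp5b 1.91-fold, Cox7a2 1.78-fold and Cox5a 1.67-fold higher. The immediate early list had a median of -0.28, with Ier2 3.34-fold, Dusp1 1.62-fold and Jun 1.57-fold lower. With the filter at the 75th percentile the immediate early median was -0.45. The osteoblast and stroma list did not stand apart, at a median of -0.04, with 5 of its 15 genes at least 2-fold lower.

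Further genes at the low end were Rnu3b1, Rnu3b2 and Rnu3b3 (each 7.73-fold lower, with equal levels) and mt-Tk (6.92-fold). At the high end were Snord72 (5.50-fold), the ribosomal protein pseudogenes Rpl10-ps6 and Rpl10-ps1 (each 3.58-fold), Mir669b (3.48-fold), Mir467e (3.27-fold), the olfactory receptor pseudogene Olfr1456-ps1 (3.10-fold), Mir297c (2.97-fold) and Mxi1, a repressor that opposes Myc (2.95-fold). With the mean of each gene's clusters Mxi1 and Mir467e were under 2-fold, at log2 differences of 0.69 and 0.79. Of 35 lists 6 stood apart, 5 above and 1 below, and the medians of the other 29 lay between -0.12 and 0.18. Of the 673 genes 70 were protein-coding, 35 higher and 35 lower, and 263 were snRNA genes, 261 of them lower. A further 121 were pseudogenes, 77 higher and 44 lower.

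**Figure D2:**
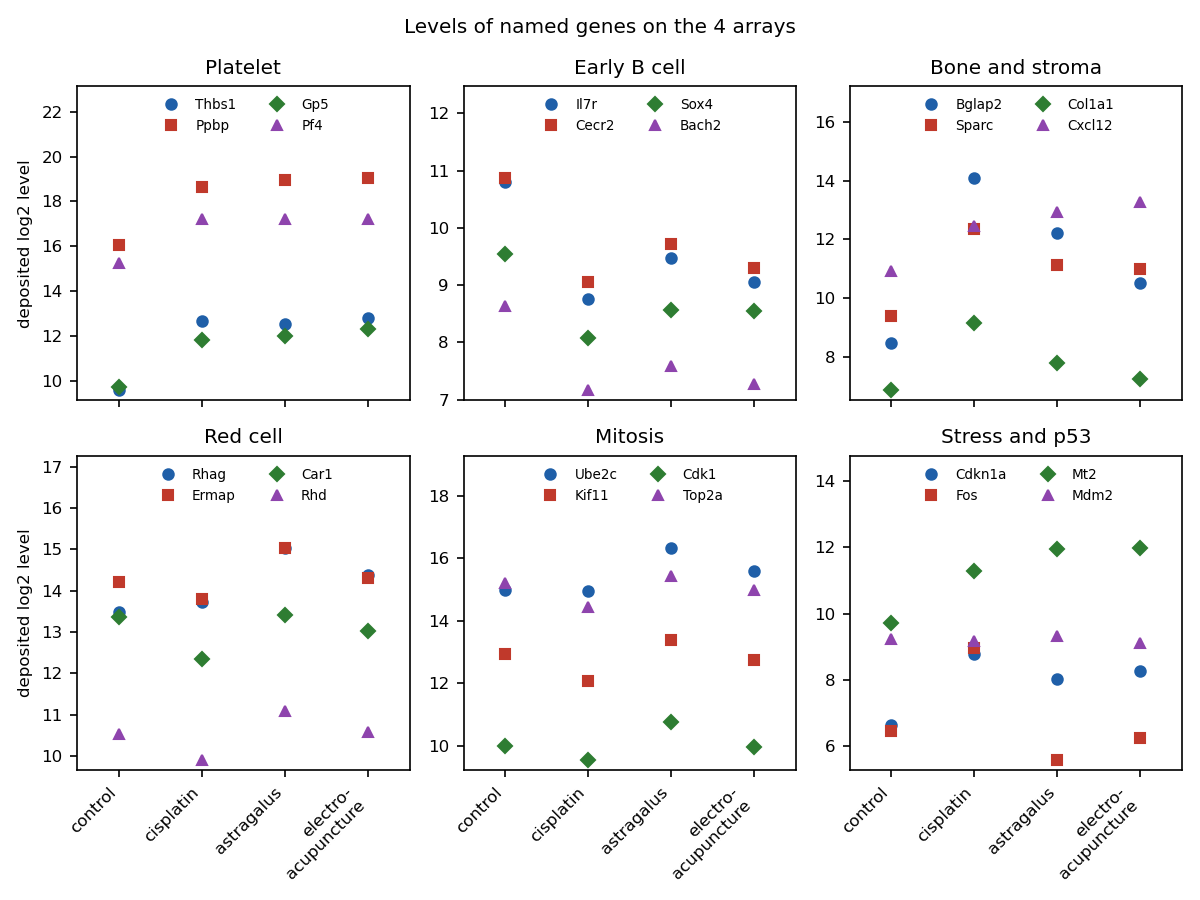
Deposited log2 levels of 24 genes on the 4 arrays, 1 point per gene and array. The platelet genes shown are lowest and the early B cell genes shown highest in control. Bglap2, Sparc and Col1a1 are highest in cisplatin, and Cxcl12 runs from 10.91 in control to 13.28 in electro-acupuncture.

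Whether the astragalus and electro-acupuncture arrays lie nearer the control than the cisplatin array was counted over the genes that differed at least 2-fold between those 2. In astragalus 92 of 512 genes (18.0%, Wilson interval 14.9 to 21.5%) lay nearer the control. In electro-acupuncture 92 of 511 genes (18.0%, 14.9 to 21.6%) did, 1 gene lying at the midpoint. By direction, the astragalus share was 11.6% for genes higher in cisplatin and 31.3% for genes lower in cisplatin, and the electro-acupuncture shares were 14.8% and 24.7%. Values beyond the cisplatin level, away from control, were seen for 284 of the genes in astragalus and 259 in electro-acupuncture. Simulated unchanged arrays gave 50.3% with equal noise and 74.4% with cisplatin noise 1.5 times as large. Control noise 1.5 and 2 times as large, simulated after the counts were seen, gave 25.5% and 15.4%. These settings gave 623 and 1267 genes at least 2-fold different, against the 512 counted, so neither matched both count and share. The simulations do not decide between a noisy control array and treatment effects. Among single genes, Bglap was at 8.96 in control, 13.68 in cisplatin, 11.95 in astragalus and 10.45 in electro-acupuncture, and Il7r at 10.81, 8.76, 9.47 and 9.05 in the same order. Thbs1 stayed close to its cisplatin level, at 9.61, 12.70, 12.53 and 12.80, and Ppbp was at 16.06, 18.63, 18.96 and 19.04. Of the 17 platelet genes 10 were higher and 6 lower than in cisplatin in astragalus, and 9 were higher and 7 lower in electro-acupuncture.

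Astragalus and electro-acupuncture differed from cisplatin in overlapping genes. Of the 344 and 228 genes at least 2-fold higher, 101 were higher in both, and 4 genes higher in astragalus were lower in electro-acupuncture. Of the 330 and 445 lower genes, 267 were lower in both. Among protein-coding genes 14 were higher in both and 16 lower in both. Unchanged arrays of equal noise gave 3.81 and 3.97 with noise drawn from protein-coding genes, and 14.0 and 13.4 with noise drawn from all genes. With cisplatin noise 1.5 times as large the first gave 27.8 and 27.2, so these counts alone do not separate a shared difference from a noisy cisplatin array. That noise setting also gave 74.4% of genes nearer the control, where astragalus and electro-acupuncture each had 18.0%. Genes at least 2-fold from all 3 other arrays numbered 37 in cisplatin, 38 in astragalus and 36 in electro-acupuncture. The 16 lower genes include, chosen after their values were seen, Apol11b, Apol11a, Apol10a, Bglap, Bglap2, Col1a1, Col1a2, Sparc, Fos, Ier2, Prg2, Cdo1 and G0s2. The 14 higher genes include, chosen in the same way, Mxi1, Pglyrp1, Tuba4a, the proteasome subunit genes Psma5 and Psmb7, the complement inhibitor gene Serping1 and the leukocyte tetraspanin gene Cd53.

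Across the 17196 genes, which are not independent replicates, the differences from cisplatin correlated at r = 0.68 (rho 0.53) with a covariance of 0.134. Both comparisons share the cisplatin array, and unchanged arrays of equal noise gave r = 0.50, a covariance of 0.0626 and 49.3 genes shared in direction. With cisplatin noise 1.5 times as large the simulation gave a covariance of 0.140 and 275 shared genes, with r = 0.69, and with noise 2 times as large it gave 0.249, 727 genes and r = 0.80. Part of the overlap may therefore come from the shared array. Pairs of differences that share no array, astragalus minus cisplatin with electro-acupuncture minus control and the reverse, correlated at 0.50 and 0.44 across genes (rho 0.29 and 0.27, covariances 0.126 and 0.114). Unchanged arrays gave correlations of 0.00 by construction, because noise was drawn separately for each array and gene. A shift of a whole gene class on both arrays also gives a positive correlation. The snRNA genes, for one, had medians of -0.64 in astragalus and -0.82 in electro-acupuncture against cisplatin. These correlations therefore do not separate a treatment effect from other shared shifts.

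Against the control array, astragalus and electro-acupuncture also had higher platelet and stromal and lower B cell medians, as cisplatin did, though single genes differed in size. In astragalus all 17 platelet genes were higher, with a median 2.25-fold difference, and in electro-acupuncture all 17 were, with a median of 2.01-fold. Early B cell genes had medians of -0.74 in astragalus and -0.96 in electro-acupuncture. Osteoblast and stroma genes had medians of 0.93 and 0.90. The 3 arrays share the control array as their reference.

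Astragalus differed at least 2-fold from control in 1516 genes, 1055 higher and 461 lower. The share of higher genes was 69.6% as deposited, 58.9% after quantile normalization and 47.6% after loess. By type, 461 of the genes were protein-coding, 427 higher and 34 lower, and 612 were pseudogenes, 559 higher and 53 lower. The stefin genes led, with Stfa2l1 28.1-fold, Stfa1 26.4-fold, Stfa2 22.5-fold, Cstdc6 16.3-fold and Stfa3 14.7-fold higher. The lowest were Rnu5g (53.8-fold lower), Snord17 (17.5-fold), Rnu1a1 (10.3-fold), Rmrp (8.22-fold) and Rnu1b6 (7.57-fold). Lists above random lists were platelet (Thbs1 7.57-fold, Ppbp 7.46-fold), neutrophil primary granule (median 0.89, Mpo 4.14-fold, Ctsg 4.03-fold), osteoblast and stroma (Bglap2 13.5-fold, Bglap 7.94-fold) and fat cell genes (0.40, Scd1 4.26-fold, Adipoq 2.95-fold). The others above were endothelial (0.23, Stab2 1.79-fold, Vwf 1.74-fold), NRF2 and metallothionein (0.71, Gstm1 5.39-fold, Mt2 4.72-fold), hypoxia and glycolysis (0.34, Pgk1 2.66-fold, Ldha 1.69-fold) and respiratory chain genes (0.87, Cox7a2 4.35-fold, Ndufa4 3.81-fold). Without the filter on low values the fat cell list did not stand apart, at a median of 0.09. After loess the medians were 0.50 for respiratory chain, 0.46 for NRF2 and metallothionein and -0.50 for mature B cell genes, and after quantile normalization 0.34 for endothelial genes. At the 75th percentile they were 1.48 for stroma, 1.22 for fat cell and 0.67 for hypoxia genes. Below random lists were early B cell (Il7r 2.53-fold, Cecr2 2.22-fold lower) and mature B cell genes (-0.30, Ms4a1 2.40-fold, Spib 2.25-fold lower). The red cell membrane and enzyme list (0.49, random lists 0.33) and the G2/M list (0.45, random lists 0.34) did not stand apart against control.

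Electro-acupuncture differed at least 2-fold from control in 1250 genes, 715 higher and 535 lower. By type, 366 were protein-coding, 306 higher and 60 lower, and 391 were pseudogenes, 337 higher and 54 lower. The highest were Rpl10-ps6 (9.51-fold), Rpl10-ps1 (9.38-fold), Thbs1 (9.13-fold), Apol11b (9.06-fold) and Ppbp (7.89-fold). The lowest were the spliceosomal RNA genes Rnu5g (27.9-fold lower), Rnu1a1 (11.0-fold), Rnu1b1 and Rnu1b2 (each 8.40-fold) and Snord17 (8.11-fold). Lists above random lists, besides platelet and stroma (Cxcl12, the chemokine that holds blood-forming cells in the marrow, 5.17-fold, Bglap2 4.17-fold), were neutrophil primary granule (median 0.83, Ctsg 3.63-fold, Mpo 2.93-fold), macrophage (0.37, Hmox1 3.27-fold, Vcam1 2.95-fold) and endothelial (0.33, Vwf 1.79-fold, Stab2 1.71-fold). The respiratory chain list (0.62, Ndufb9 3.84-fold, Cox7a2 3.76-fold) and the NRF2 and metallothionein list (0.40, Mt2 4.89-fold, Gstm1 3.56-fold) were also above. With the filter at the 75th percentile the macrophage list did not stand apart, at a median of 0.31, and the stroma and NRF2 medians were 1.51 and 0.85. Without a filter the stroma median was 0.48. Below were early B cell (Il7r 3.39-fold, Cecr2 2.97-fold lower), mature B cell (-0.48, Spib 3.05-fold, Ms4a1 2.25-fold lower) and mitotic genes (-0.19, Cenpf 1.79-fold, Kif23 1.71-fold lower). The share of higher genes was 57.2% as deposited and 49.6% after loess.

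Astragalus and electro-acupuncture were the closest pair by the count of genes and by correlation (r = 0.991), though not by the robust spread of differences (0.282 against 0.267 for electro-acupuncture and cisplatin), with 263 genes at least 2-fold different, 113 higher and 150 lower in astragalus. Stefin genes, red cell genes and mitotic genes were higher in astragalus, and macrophage genes were higher in electro-acupuncture. Stfa2l1 was 7.11-fold, Stfa2 6.87-fold, Stfa3 4.82-fold, Stfa1 3.86-fold and Cstdc6 3.48-fold higher in astragalus. All 31 mitotic genes (median 0.65, Ccnb2 1.96-fold, Cenpf 1.95-fold), all 21 red cell membrane and enzyme genes (0.50, Ank1 1.71-fold, Sptb 1.67-fold) and all 18 erythroid regulators (0.41, Trim10 1.74-fold, Tspan33 1.65-fold) were higher. Neutrophil secondary and tertiary granule genes had a median of 0.54 and basophil and mast cell genes one of 0.22 (Prss34 1.34-fold, Mcpt8 1.29-fold). The basophil list did not stand apart after quantile normalization or loess, at medians of 0.16 and 0.12. After loess the medians were also smaller for mitotic (0.37), red cell (0.30), erythroid regulator (0.16) and granule genes (0.35), and -0.23 for platelet genes. Random lists matched in level to the erythroid regulators had a median of 0.24. Below random lists were macrophage (-0.25, Hmox1 1.79-fold lower, C1qb at 4.98, under the floor, against 6.25), immediate early (-0.15, Fos 1.57-fold, Zfp36 1.35-fold lower) and platelet genes, whose median was 0.00 against 0.23 in random lists of like level, with Gp9 1.42-fold and P2ry12 1.38-fold higher. The lowest genes were Mir466o (4.59-fold lower), the olfactory receptor gene Olfr1346 (4.11-fold), Mir467h (4.03-fold), Mir669b (3.86-fold) and Mir466d (3.43-fold). The share of higher genes was 43.0% as deposited, 26.9% after quantile normalization and 21.3% after loess, but 59.6% (102 higher, 69 lower) with the filter at the 75th percentile. Of the 263 genes 50 were protein-coding, 27 higher and 23 lower, 60 were pseudogenes, 42 of them higher, and 77 were microRNA genes, 70 of them lower.

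Genes given whatever their values had small differences in most cases. Actb (beta-actin) was at 17.55 in control and 17.67 on each other array, and Gapdh at 10.65, 11.27, 11.34 and 11.27 in control, cisplatin, astragalus and electro-acupuncture. In the same order Alas2, the first enzyme of heme synthesis in red cells, was at 14.64, 14.99, 15.39 and 15.00, and Epor, the erythropoietin receptor, at 8.51, 8.22, 8.51 and 8.01. Kit, the stem cell factor receptor, was at 6.77, 6.79, 6.85 and 6.72, and Xist, the RNA of the inactive X chromosome, at 6.56, 6.61, 6.55 and 6.94. Cdkn1a was at 6.64, 8.76, 8.03 and 8.27, and Mdm2 at 9.22, 9.18, 9.31 and 9.11. Of the minor globin genes and pseudogenes with clusters of their own, Hbb-bh0 was at 7.60, 7.17, 7.01 and 8.13, which is 2.17-fold lower in astragalus than in electro-acupuncture. In that order Hba-ps4 was at 10.63, 10.73, 10.73 and 10.80, Hbb-bh2 at 5.47, 5.95, 5.58 and 5.63, Hbb-bh3 at 5.80, 5.48, 5.80 and 5.96, and Hbb-y at 6.07, 5.70, 5.91 and 6.32.

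For 251 genes a pair of clusters above the floor gave a repeat measurement within the arrays. Across those genes the differences from the 2 clusters correlated at 0.66 for cisplatin against control, 0.88 for astragalus against cisplatin and 0.90 for electro-acupuncture against cisplatin. Against control they correlated at 0.91 for both astragalus and electro-acupuncture, and the lowest value was 0.56, for astragalus against electro-acupuncture. Of the genes at least 2-fold different by their first cluster, 11 of 12, 57 of 59 and 58 of 61 had the same sign by their second. Chance would give 50% only if both signs were equally common. Of the snRNA genes at least 2-fold different from cisplatin, 152 of 155 in astragalus and 261 of 263 in electro-acupuncture were lower. Where such genes are many, unrelated clusters would also often share a sign. Genes with 2 clusters include small RNA genes such as Rnu5g, Rnu1a1 and Rn5s, whose clusters may measure near-identical sequences. The 59 of 251 for astragalus against cisplatin compare with 3.92% of all genes, so these genes are not typical. The agreement thus checks the arrays' signal for such genes only, and it says nothing of the spread between mice.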

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

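The setting with protein-coding genes only was chosen after the data were seen, and the other settings were planned. With protein-coding genes only, the genes at least 2-fold different numbered 192 for cisplatin and control, 128 for astragalus and cisplatin, 70 for electro-acupuncture and cisplatin, 461 for astragalus and control, 366 for electro-acupuncture and control and 50 for astragalus and electro-acupuncture, and 30 genes were shared against cisplatin in place of 368. This setting compares 11226 in place of 17196 genes. With the filter at the 75th percentile, 171 genes differed between astragalus and electro-acupuncture, and the shares nearer the control were 14.6% in astragalus and 13.3% in electro-acupuncture. That filter keeps 9226 genes, and the cause of the lower shares was not tested. Of the recomputed counts and shares these 10 moved and 110 stayed close. Counts by direction moved in 18 cases and stayed in 78, and 12 of those that moved were with protein-coding genes only. Among list medians 434 kept their call, 10 lost it and 0 turned sign. Among values of named genes 2371 kept their side of 2-fold, 31 went under it, 8 went above it and 0 turned sign. No scaling moved the median of all genes by over 0.1. Planned settings that were not run are the pseudocounts, because the values are already on a log scale, and leaving out probe sets by the ending of their identifiers, because none has such an ending. No paired analysis was possible because each group had 1 array. Leaving out 1 array at a time was not possible for the same reason.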

Other observations

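The tests and gene classes in this part were chosen only after the values were seen. The stefin gene cluster, whose products inhibit cysteine proteases and are abundant in neutrophils, differed strongly between the arrays. Its 10 measured genes had a median log2 difference from control of 2.64 in cisplatin, 3.63 in astragalus and 1.66 in electro-acupuncture. Stfa2l1 was at 12.15 in control, 15.67 in cisplatin, 16.96 in astragalus and 14.13 in electro-acupuncture. Of 5 apolipoprotein L genes, Apol11b was at 7.99, 13.37, 10.97 and 11.17 in the same order and Apol11a at 6.71, 10.47, 8.76 and 8.84. Genes of both clusters have close copies, so the signal of single members is uncertain. The 27 replication-dependent histone genes had a median of 0.54 in astragalus against control, above random lists of like level, and one of 0.12 in cisplatin, within them. Jchain, which joins IgA and IgM chains, was at 8.51 in astragalus and at 6.58, 7.27 and 7.26 in control, cisplatin and electro-acupuncture.

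Protein-turnover and folding genes had higher medians on each of the 3 other arrays than on the control array. The 39 proteasome genes had medians of 0.22 in cisplatin, 0.84 in astragalus and 0.61 in electro-acupuncture. In the same order the 13 chaperonin and prefoldin genes had medians of 0.32, 1.03 and 0.81, the 78 mitochondrial ribosome genes 0.15, 0.38 and 0.32, and the 209 ribosomal protein pseudogenes 0.39, 0.89 and 0.57. The 15 cholesterol synthesis genes had medians of 0.01, 0.30 and 0.20. Among small RNA genes the 586 snRNA genes had medians of -0.09, -0.78 and -0.94, the 546 snoRNA genes -0.13, -0.27 and -0.03, and the 533 microRNA genes -0.14, -0.24 and 0.11. The 181 olfactory receptor genes had medians of -0.10, -0.25 and 0.05. In astragalus against control, random lists of like level had medians of 0.21 for proteasome and 0.22 for chaperonin and prefoldin genes. They had 0.085 for mitochondrial ribosome genes and 0.38 for ribosomal protein pseudogenes. Part of the astragalus medians of these classes may thus go with level alone.

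The first pattern is that platelet, stromal and fat cell genes were higher and B cell genes lower than in the control array. A smaller share of the main blood cells would raise the genes of every other cell type alike. In cisplatin and astragalus against control, the upper quartiles of 4 other lists (monocyte, stem cell, plasma cell and osteoclast) lay below the platelet and stromal medians. This held in each planned setting, most closely at 0.51 against 0.63 for stroma in astragalus. The neutrophil primary granule list was not among those 4. Its upper quartile in astragalus was 1.64, above the platelet (1.17) and stromal (0.93) medians. In cisplatin it was 1.03, below the medians of 1.11 and 1.16 but above the stromal median of 0.72 without a filter. With that list counted, the explanation stays open in both arrays. In electro-acupuncture it stays open with the 4 lists alone. Their highest upper quartile there was 0.92 against a stromal median of 0.90 (0.83 against 0.48 without a filter). At the 75th percentile it was 1.36 against a platelet median of 1.21. The explanation also stays open for fat cell genes, whose median in electro-acupuncture was 0.10 without a filter. A control array or pool that stands apart on its own cannot be told apart from an effect that the 3 treatments share, because each group has 1 array. In the control array 309 genes were at least 2-fold from all 3 others, against at most 38 in any other array. A response to cisplatin in all 3 groups is a biological reading that may also hold, and it was not tested because the labels do not say which mice received the drug.

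The second pattern is that respiratory chain and proteasome genes were higher and snRNA genes lower than in the control array. A preference for genes of short genomic span would place the respiratory chain median of electro-acupuncture against control within random protein-coding lists matched on level and span, but it was at percentile 99.6, at 0.62 against 0.23 in matched lists. Across 11226 genes the difference from control correlated with genomic span at rho -0.16 in electro-acupuncture and 0.02 in astragalus. Span may thus account for part of the pattern in electro-acupuncture. The wider range of the astragalus array is not shared by the electro-acupuncture array, where the respiratory chain median was 0.60 with the loess trend removed. For the snRNA part, a loss of RNA without a poly(A) tail would also lower histone genes, whose medians were 0.16 in electro-acupuncture and 0.54 in astragalus against control. Replication genes had medians of 0.21 and 0.53 there, so a rise of histone genes with them could mask such a loss. In the same order snoRNA genes had medians of -0.03 and -0.27 and microRNA genes 0.11 and -0.24. The histone values therefore cannot exclude the loss. A treatment effect and other differences in RNA handling between the 4 preparations remain open and untested.

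The third pattern is that red cell and G2/M genes were higher in the astragalus array than in the cisplatin and electro-acupuncture arrays. If the wider signal range of that array were the whole cause, both lists would fall among random lists of like level. The smallest percentile of the 2 lists in the 2 comparisons was 99.99 as deposited and 100 with the loess trend removed. The random lists were already matched on level, so removing the trend adds little as a test. The range may account for part, as the red cell median against cisplatin went from 0.77 to 0.47 with the trend removed. A gain in all abundant blood cell genes would lift platelet genes too, but their upper quartile was at most 0.20 in the 2 comparisons, below the red cell lower quartile of at least 0.41. Neutrophil secondary and tertiary granule genes were higher against electro-acupuncture (0.54), but against cisplatin (0.37) they did not stand apart. Against control neither list stood apart in astragalus (0.49 and 0.45), and low values in cisplatin (-0.21 and -0.40) may account for part, as may a low G2/M median (-0.19) but not the red cell one (0.04) in electro-acupuncture, while no biological explanation was tested.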
